A study of Mus musculus with 18 samples.

How the data were processed

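Total RNA from 18 samples of cultured mouse neurospheres was measured on Affymetrix mouse gene arrays, 1 array per sample. Per the labels, the RNA was extracted with Trizol and purified on silica columns, and the arrays carried a biotin label. The samples fell into 6 groups of 3, which were wild type, Pcdh19 knockout and mosaic cultures (a mix of wild type and knockout cells), each at day 0 and at day 4 of differentiation. The design text calls the replicates technical, and nothing in the labels ties them to separate animals or cultures. All p-values here therefore measure only the spread between these samples.

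The deposited values are normalized expression values per probe set on a log2 scale, as read from the values themselves. They ran from 0.722 to 13.97 over 41345 probe sets, with array medians of 4.85 to 4.99. A maximum above 11.09, the natural log of the highest 16 bit intensity, rules out natural logs of scanner intensities. The method of normalization, the background correction and the log base are not given in the sources used here. Log2 fold changes assume base 2. No scanner files were used here, so no background level or detection call was at hand. The median standard error of a log2 fold change was 0.126 between groups and 0.178 for a difference of differences.

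Probe sets were named from the platform annotation given with the series. Of the 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had no listed symbol, and only those with 1 symbol were used. Symbols were looked up through their Entrez identifiers in a RefSeq gene table of mouse assembly GRCm38.p6. The lookup matched 23328 probe sets, did not match 193, and updated 0 symbols. That table served only for names and for the genes that neighbour Pcdh19. Each of 22180 genes was represented by its probe set with the highest mean over the 18 arrays. Genes were kept when their value lay above the 25th percentile of its array on at least 3 arrays, which left 19016 genes and dropped 3164. Of the tested genes, 1052 had several probe sets. Of the 407 among them that were called in wild type differentiation, 134 had probe sets of opposite sign. The probe sets of Hes5 differed in this way.

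All tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. A linear model with a mean for each of the 6 groups was fitted to all 18 arrays, so that every comparison shared 1 estimate of the spread with 12 residual and 4.36 prior degrees of freedom. Moderated two-sided tests (lmFit and eBayes) were adjusted with the Benjamini-Hochberg method over the 19016 genes, and a gene was called at an adjusted p under 0.05. There were 12 contrasts, made up of 3 for differentiation, 6 between genotypes within a day and 3 differences of differentiation between genotypes. Genes whose mosaic level lay outside both genotypes were sought by taking the larger p of the mosaic contrasts with wild type and with knockout, where both had the same sign. Errors given with log2 fold changes are standard errors from the fit, and errors given with group means are SDs.

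A total of 29 gene lists were tested in each contrast with limma's camera, at a preset correlation between genes of 0.01, and adjusted over all 348 tests. Each was tested again with an estimated correlation and with fry. Counts of list members are given over all genes tested and adjusted over the list alone. The groups, the model, the filters, the gene lists, the thresholds and the rule for naming genes were set before the data were examined. By that rule the text names Pcdh19, the 6 highest and the 6 lowest log2 fold changes among called genes whose replicates did not overlap between the groups, and up to 4 called members of each list described. Predicted genes, clone names and olfactory, vomeronasal and small RNA genes were left out of the highest and lowest, and where no member of a list passed, members could be named to give values. Any other gene is said to have been chosen after its values were seen.

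The model was tested on simulated data before use. For knockout against wild type at day 0, simulated over 19016 genes, it recovered 41 of 67 genes changed 1.5-fold, 63 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 17 false calls and 0 calls of the wrong sign. For the mosaic outside both genotypes at day 4 it recovered 38 of 67, 58 of 67 and 66 of 66, with 1 false call. With fewer genes changed the threshold is stricter, so these rates do not carry over to counts of 0. In a simulated day 0 list test, a list moved by 0.3 (log2) passed and 0 unmoved did. Correlation between members was not simulated.

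The alternatives tried were quantile normalization, a common array median, no filter, a filter at the 50th percentile, the mean of a gene's probe sets, the replicate number as a block, a variance trend with robust estimation, array weights, a fit on the groups compared alone, a minimum change of 1.5-fold, an adjusted p under 0.01, and leaving out each array in turn. Added after seeing the data were the removal of the day 4 array with the lowest weight in each genotype, contrasts averaged over both days, and list tests and differences of list means without each array. Probe sets with several symbols or no listed symbol were left out because they could not be tied to 1 gene. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.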

Results

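Gene expression was measured in neurospheres, which are free-floating clusters of cultured neural stem and progenitor cells, and in the cells obtained from them after 4 days of differentiation. The cultures were wild type, Pcdh19 knockout or a mosaic of both. Pcdh19 is an X-linked gene for a protocadherin, a protein of cell to cell adhesion, and in humans its mutation causes an epilepsy that affects females who carry a mixture of mutant and normal cells. The design therefore asks how loss of the gene, and the mixing of both kinds of cell, bear on differentiation of neural progenitors. There were 6 groups of 3 arrays, and 19016 genes were tested. Pearson's r over probe sets was 0.981 to 0.986 between arrays of a group and 0.955 to 0.972 between arrays of different days. The first principal component held 61.2% of the variance and parted the days, and the second held 6.26%. Precision was limited by 3 technical replicates per group, and p-values measured only their spread. Lists called with the preset correlation held with an estimated correlation for 3 of 97 calls, which were the immediate early genes in differentiation of each genotype.

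Pcdh19 signal was lower in knockout than in wild type arrays on both days and intermediate on average in the mosaic. At day 0 the log2 signal was 6.78 ± 0.11 (SD, n = 3) in wild type, 5.51 ± 0.15 in knockout and 6.0 ± 0.33 in mosaic cultures. At day 4 it was 6.90 ± 0.09, 5.70 ± 0.17 and 6.38 ± 0.79. The knockout lay below the wild type by a log2 difference of -1.27 ± 0.26 (SE) at day 0 and -1.20 ± 0.26 at day 4, with every knockout array below every wild type array. Over all genes neither passed in limma (adjusted p = 0.855 and 0.195), whose shared spread includes the wider mosaic SDs. In a fit on the day 0 wild type and knockout arrays alone that day's difference passed (SE 0.106, adjusted p = 0.0445). Mosaic arrays differed from wild type by -0.78 at day 0 and -0.51 at day 4 (adjusted p = 0.999 and 0.351). From knockout they differed by 0.49 and 0.69 (adjusted p = 1 and 0.797). Mosaic replicates 1, 2 and 3 at day 4 measured 6.54, 7.09 and 5.52, so replicate 3 lay at the level of the knockout arrays (5.53 to 5.86) and replicate 2 above all 3 wild type arrays (6.81 to 6.98). The share of wild type cells in each mosaic sample is not given in the sources used. Without replicate 3 the mosaic differed from wild type by -0.08, and without replicate 2 by -0.86. From knockout it differed by 1.12 and 0.34. Over differentiation Pcdh19 passed in no genotype, with log2 fold changes of 0.12, 0.19 and 0.39 in wild type, knockout and mosaic (adjusted p = 0.753, 0.674 and 0.333). Which part of the gene was deleted, and whether the probe set lies in it, is not given, so the probe set may check nothing about the labels.

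**Figure D1:**
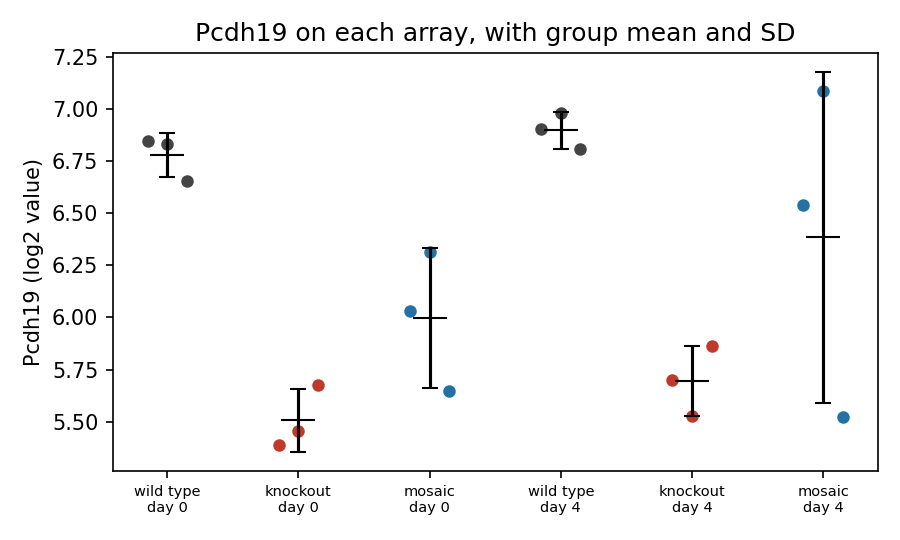
Log2 signal of Pcdh19 (vertical axis) on each of the 18 arrays, by genotype and day, where dots are arrays, bars are group means and whiskers are SDs. Knockout arrays lie below wild type arrays on both days, and the mosaic arrays at day 4 spread from 5.52 to 7.09.

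Differentiation of wild type neurospheres, the comparison of day 4 with day 0, raised oligodendrocyte genes and lowered immediate early and cell cycle genes. Mobp and Mag, which encode myelin proteins, rose by 4.97 ± 0.23 (31.4-fold) and 4.88 ± 0.35 (29.3-fold) on the log2 scale (SE, n = 3 per group). Mal, Ermn, Cldn11 and Mbp, also made by myelinating cells, rose by 3.87, 3.75, 3.23 and 3.08. Fos and Egr1, transcription factors induced within minutes of a stimulus, fell by 5.48 ± 0.12 and 4.65 ± 0.14, and Nr4a1 fell by 3.89. The chaperone gene Hspa1a fell by 4.29 ± 0.43, the monooxygenase-like gene Moxd1 by 4.40 and Fbln2, an extracellular matrix protein, by 3.94. These were the 6 highest and 6 lowest changes under the naming rule, with adjusted p between 1.99e-14 and 1.34e-06 and no overlap between arrays of the days. In all, 6386 of 19016 genes passed, 3280 higher and 3106 lower at day 4, and 793 of them changed at least 2-fold (263 up, 530 down). After quantile normalization 4092 genes were higher and 2556 lower, so the share of higher calls was 61.6% in place of 51.4%.

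Among lists of cell types in wild type cultures, 21 of 23 oligodendrocyte genes rose, 0 fell and 2 did not pass (22 rose adjusted over the list alone), with Mobp, Mag, Mal and Ermn leading. The list was higher by camera with adjusted p = 2.72e-17, and adjusted p = 0.0755 with an estimated correlation. Of 19 genes of oligodendrocyte progenitors 11 rose and 1 fell (12 and 2 adjusted over the list alone), among them C1ql1 (1.25), Gpr17 (1.18), Tnr (0.88) and Pdgfra (0.79), with adjusted p = 0.00354, and adjusted p = 0.479 with an estimated correlation. Neuronal genes rose in 19 of 29 cases and fell in 0 (20 and 0 adjusted over the list alone). The RNA-binding protein gene Elavl3 rose by 2.08, the kinesin gene Kif5c by 1.26 and the neurofilament-related Ina by 1.13, and the list had adjusted p = 9.09e-06, and adjusted p = 0.403 with an estimated correlation. Of 29 astrocyte genes 17 rose and 6 fell (18 and 6 adjusted over the list alone). Clu and S100b rose by 2.12 and 1.87 while Gfap, the intermediate filament of astrocytes, fell by 1.68 and Agt by 1.60, and the list was higher with adjusted p = 0.00753, and adjusted p = 0.691 with an estimated correlation.

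Neural stem cell and cell cycle genes went the other way in wild type cultures. Cell cycle genes fell in 24 of 28 cases and rose in 0 (25 and 0 adjusted over the list alone), with Aspm, Ccnb2, Bub1 and Nusap1, all of mitosis, lower by -2.74, -2.73, -2.62 and -2.56. The list had adjusted p = 1.42e-17, and adjusted p = 0.343 with an estimated correlation. Of 24 neural stem cell genes 10 fell and 2 rose, the same counts adjusted over the list alone. Tnc, Hes1, Hes5 and Nes fell, with log2 fold changes of -2.86, -2.56, -1.91 and -1.58, although a dimmer probe set of Hes5 gave 0.15. This list had adjusted p = 0.0126, and adjusted p = 0.46 with an estimated correlation. In the Notch pathway 12 of 23 genes fell and 1 rose (12 and 2 adjusted over the list alone), among them the effector genes Hes1, Hey2 (-2.42), Hes5 and Hey1 (-1.39), with adjusted p = 0.000118, and adjusted p = 0.343 with an estimated correlation.

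Immediate early genes fell in 20 of 22 cases in wild type cultures and rose in 0 (21 and 0 adjusted over the list alone), led by Fos, Egr1, Nr4a1 and Fosb (-3.71), with adjusted p = 2.79e-23, and adjusted p = 0.00708 with an estimated correlation. Of 24 genes of stress and of the unfolded protein response 19 fell and 1 rose (21 and 1 adjusted over the list alone), among them Hspa1a, Hspa1b (-3.24), the endoplasmic reticulum chaperone gene Hspa5 (-2.36) and Atf3 (-1.93), with adjusted p = 4.03e-11, and adjusted p = 0.0755 with an estimated correlation. Hypoxia and glycolysis genes fell in 14 of 21 cases and rose in 2 (15 and 2 adjusted over the list alone), with Adm, Vegfa, Ero1a and Ldha at -2.08, -2.04, -1.69 and -1.44, adjusted p = 1.71e-06, and adjusted p = 0.403 with an estimated correlation. Of 30 extracellular matrix genes 14 fell and 5 rose (14 and 6 adjusted over the list alone), including Lgals1 (-3.41), Tnc, Adamts1 (-2.32) and Fn1 (-1.78), with adjusted p = 0.00813, and adjusted p = 0.0833 with an estimated correlation. Of 18 targets of p53, 10 fell and 3 rose both over all genes and adjusted over the list alone, among them Plk2, Cdkn1a, Eda2r and Fas (-1.55, -1.38, -1.19 and -0.83), with adjusted p = 0.0314, and adjusted p = 0.607 with an estimated correlation. That call ended without wild type day 0 replicate 2 (0.057), day 4 replicate 2 (0.0567) or day 4 replicate 3 (0.0553).

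In the wild type, 12 of 19 genes of cholesterol synthesis rose and 1 fell (15 and 2 adjusted over the list alone). The enzymes Lss, Mvd and Mvk rose by 0.90, 0.83 and 0.74 and Insig1, a sterol sensor that restrains the pathway, fell by 0.97. The call of Lss ended without wild type day 0 replicate 1 (0.0566) or 3 (0.0614). The list had adjusted p = 0.0218, and adjusted p = 0.85 with an estimated correlation. Among neighbours of Pcdh19 on the X chromosome 11 of 21 fell and 2 rose, also adjusted over the list alone. Drp2 rose by 1.55 while Cenpi (-1.22), Gla (-1.05) and Armcx3 (-0.97) fell, with adjusted p = 0.00852, and adjusted p = 0.376 with an estimated correlation. Of 6 sex-linked marker genes 5 fell and 0 rose, also adjusted over the list alone, namely Kdm6a (-1.02), Kdm5d (-0.89), Uty (-0.61), Eif2s3y (-0.45) and Ddx3x (-0.38), with adjusted p = 0.0015, and adjusted p = 0.343 with an estimated correlation. The call of Eif2s3y ended without wild type day 0 replicate 1 (0.0624) or day 4 replicate 1 (0.0809). Cross-hybridisation from X-linked homologues was not excluded for Uty and Eif2s3y. The other 14 lists did not pass as sets in the wild type. Synapse genes rose in 10 of 26 cases and fell in 2, with Syt1, Gabrb1 and Sv2a at 2.45, 1.93 and 1.42 and Lrrtm2 at -1.31 (adjusted p = 0.218). Intermediate progenitor and neuroblast genes rose in 5 of 21 cases and fell in 6, with Dcx and Dlx5 at 1.74 and 1.02 and Sox11 at -0.63 (adjusted p = 0.898). For that list the test pointed down while the median and mean were above 0, and the median, mean and test also differed in sign for cadherins, Wnt targets and BMP and TGF-beta targets, none of which passed. Nonclustered protocadherins rose in 4 of 12 cases and fell in 0, with Pcdh1, Pcdh17, Pcdh10 and Pcdh8 at 0.90, 0.62, 0.49 and 0.43 (adjusted p = 0.0988).

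Knockout neurospheres raised oligodendrocyte genes and lowered immediate early and stress genes over differentiation. Mag, Mobp and Mal rose by 4.79 ± 0.35, 4.62 ± 0.23 and 3.33 ± 0.21 (SE, n = 3 per group), and Enpp6, Ermn and Mbp, all of oligodendrocytes, by 3.29, 3.26 and 3.25. Fos, Egr1 and Fosb fell by 5.43 ± 0.12, 4.64 ± 0.14 and 3.95 ± 0.25, and the chaperone genes Hspa1b and Hspa1a and the gene Moxd1 had log2 fold changes of -4.15, -4.01 and -3.96. These 12 had adjusted p between 2.26e-14 and 2.57e-06 and no overlap between the days. In total 5211 genes passed, 2846 higher and 2365 lower, with 791 at least 2-fold changed (322 up, 469 down). All 23 oligodendrocyte genes rose (23 adjusted over the list alone), with adjusted p = 3.09e-21, and adjusted p = 0.0755 with an estimated correlation. Neuronal genes rose in 20 of 29 cases and fell in 0 (21 and 0 adjusted over the list alone), with Elavl3 at 2.19, Kif5c at 1.71 and Celf4 at 1.57, adjusted p = 1.09e-07, and adjusted p = 0.343 with an estimated correlation. The synapse list passed here, with 13 of 26 genes higher and 1 lower (14 and 1 adjusted over the list alone), among them Syt1, Gabrb1 and Snap91 at 2.42, 2.10 and 1.34, adjusted p = 0.00456, and adjusted p = 0.343 with an estimated correlation. Of 29 astrocyte genes 18 rose and 6 fell (19 and 6 adjusted over the list alone), with Clu at 2.36, S100b at 2.09, Glul at 1.54 and Agt at -1.67, adjusted p = 0.000573, and adjusted p = 0.559 with an estimated correlation.

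Of 19 genes of oligodendrocyte progenitors in the knockout 14 rose and 1 fell (15 and 1 adjusted over the list alone), with C1ql1 and Gpr17 at 1.63 and 1.57, adjusted p = 7.55e-06, and adjusted p = 0.343 with an estimated correlation. Protocadherins other than the clustered ones rose in 6 of 12 cases and fell in 0 (6 and 0 adjusted over the list alone), with Pcdh1 at 1.09 and Pcdh17 at 0.73, adjusted p = 0.0135, and adjusted p = 0.361 with an estimated correlation. Cell cycle genes fell in 24 of 28 cases and rose in 0, also adjusted over the list alone, with Ccnb2, Aspm, Cenpe and Mki67 at -2.99, -2.98, -2.97 and -2.82, adjusted p = 1.94e-21, and adjusted p = 0.343 with an estimated correlation. Immediate early genes fell in 19 of 22 cases and rose in 0, also adjusted over the list alone, with adjusted p = 3.78e-24, and adjusted p = 0.00708 with an estimated correlation. Genes of the interferon response fell in 7 of 23 cases and rose in 0 (8 and 0 adjusted over the list alone), with the RNA sensor genes Ifih1 and Ddx58 at -0.92 and -0.73 and Gbp3 at -0.79, adjusted p = 0.00441, and adjusted p = 0.0755 with an estimated correlation. Stress genes fell in 19 of 24 cases and rose in 1, also adjusted over the list alone, with adjusted p = 4.73e-11, and adjusted p = 0.0755 with an estimated correlation. The neural stem cell list fell with adjusted p = 0.0326, and adjusted p = 0.558 with an estimated correlation, but its median was 0.02 and its mean -0.42, with 9 of 24 genes lower and 3 higher (9 and 5 adjusted over the list alone). Of the 97 list calls it was the only 1 in which median, mean and test differed in sign.

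A further 7 lists passed in the knockout in the direction they had in the wild type. They were hypoxia and glycolysis (3 up, 14 down of 21), the Notch pathway (1 up, 9 down of 23), extracellular matrix (2 up, 13 down of 30), targets of p53 (2 up, 8 down of 18), cholesterol synthesis (11 up, 1 down of 19), sex-linked markers (0 up, 5 down of 6) and neighbours of Pcdh19 (1 up, 6 down of 21). Adjusted over the list alone the counts up and down were 3 and 14, 1 and 11, 3 and 13, 2 and 8, 15 and 2, 0 and 5, and 1 and 7. Vegfa changed by -1.99, Hey2 by -2.42, Lgals1 by -3.48, Cdkn1a by -1.61 and Lss by 1.07. In that order adjusted p was 2.4e-05, 0.000808, 0.0052, 0.0095, 0.0052, 0.00275 and 0.0179. With an estimated correlation the 7 adjusted p were 0.46, 0.361, 0.0755, 0.539, 0.826, 0.344 and 0.43.

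Differentiation of mosaic neurospheres raised oligodendrocyte genes and lowered immediate early and stress genes. Mag, Mobp and Mal rose by 5.50 ± 0.35, 5.21 ± 0.23 and 3.72 ± 0.21 (SE, n = 3 per group), and Cldn11, Mbp and Ermn by 3.70, 3.55 and 3.34. Fos fell by 5.19 ± 0.12, Hspa1a by 4.55 ± 0.43, and Fbln2, Egr1, Hspa1b and Moxd1 had log2 fold changes of -4.31, -4.13, -4.05 and -3.84. In these 12 genes the days did not overlap, and adjusted p lay between 4.74e-14 and 1.46e-06. A total of 4989 genes passed, 2729 higher and 2260 lower, and 824 changed at least 2-fold (378 up, 446 down). Oligodendrocyte genes rose in 23 of 23 cases (23 adjusted over the list alone), with adjusted p = 1.56e-24, and adjusted p = 0.0558 with an estimated correlation. Genes of cholesterol synthesis rose in 16 of 19 cases and fell in 1, also adjusted over the list alone. The enzyme genes Lss, Cyp51, Ebp and Sqle rose by 1.34, 1.03, 0.95 and 0.94, and the list had adjusted p = 2.07e-05, and adjusted p = 0.639 with an estimated correlation. Neuronal genes rose in 17 of 29 cases and fell in 0 (19 and 0 adjusted over the list alone), with Elavl3 at 2.32, Kif5c at 1.62 and Nefl at 1.43, adjusted p = 3.51e-07, and adjusted p = 0.343 with an estimated correlation. The interferon list fell with 9 of 23 genes lower and 0 higher (10 and 0 adjusted over the list alone), Gbp3 and Ddx58 both at -1.09, adjusted p = 0.00288, and adjusted p = 0.0755 with an estimated correlation.

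Immediate early genes fell in 21 of 22 cases in the mosaic and rose in 0, also adjusted over the list alone, with adjusted p = 1.56e-24, and adjusted p = 0.00708 with an estimated correlation. Cell cycle genes fell in 24 of 28 cases and rose in 0, also adjusted over the list alone, with Ccnb2, Nusap1, Cenpf and Bub1 at -2.78, -2.40, -2.38 and -2.32, adjusted p = 1.92e-18, and adjusted p = 0.343 with an estimated correlation. The synapse list rose with 9 of 26 genes higher and 3 lower (11 and 4 adjusted over the list alone), with Syt1 at 2.48 and Sv2a at 1.83, adjusted p = 0.0342, and adjusted p = 0.465 with an estimated correlation. That call ended without mosaic day 0 replicate 3 (0.056) or day 4 replicate 1 (0.0636), with the mean of a gene's probe sets (0.0626) and with the lowest-weight day 4 arrays left out (0.0691). Lists of oligodendrocyte progenitors (12 up, 0 down of 19), astrocytes (17 up, 6 down of 29) and nonclustered protocadherins (7 up, 0 down of 12) rose, with the same counts adjusted over the list alone and adjusted p = 3.61e-05, 0.000324 and 0.00469. With an estimated correlation those adjusted p were 0.343, 0.557 and 0.343. S100b rose by 2.35, Gpr17 by 1.54 and Pcdh1 by 0.85. The lists that fell besides these were stress genes (1 up, 18 down of 24), hypoxia and glycolysis (0 up, 15 down of 21), the Notch pathway (1 up, 10 down of 23), extracellular matrix (4 up, 14 down of 30), neural stem cells (3 up, 10 down of 24), targets of p53 (2 up, 8 down of 18) and sex-linked markers (0 up, 3 down of 6). Adjusted over the list alone their counts up and down were 1 and 20, 1 and 16, 1 and 10, 4 and 15, 3 and 10, 2 and 9, and 0 and 4. Their adjusted p were 2.7e-10, 4.9e-08, 5.55e-05, 0.00229, 0.00813, 0.00835 and 0.0095. With an estimated correlation those 7 adjusted p were 0.0833, 0.343, 0.343, 0.0755, 0.432, 0.524 and 0.421. Members that fell included Adm (-2.65), Hes1 (-2.28), Lgals1 (-3.43) and Nes (-1.63).

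**Figure D2:**
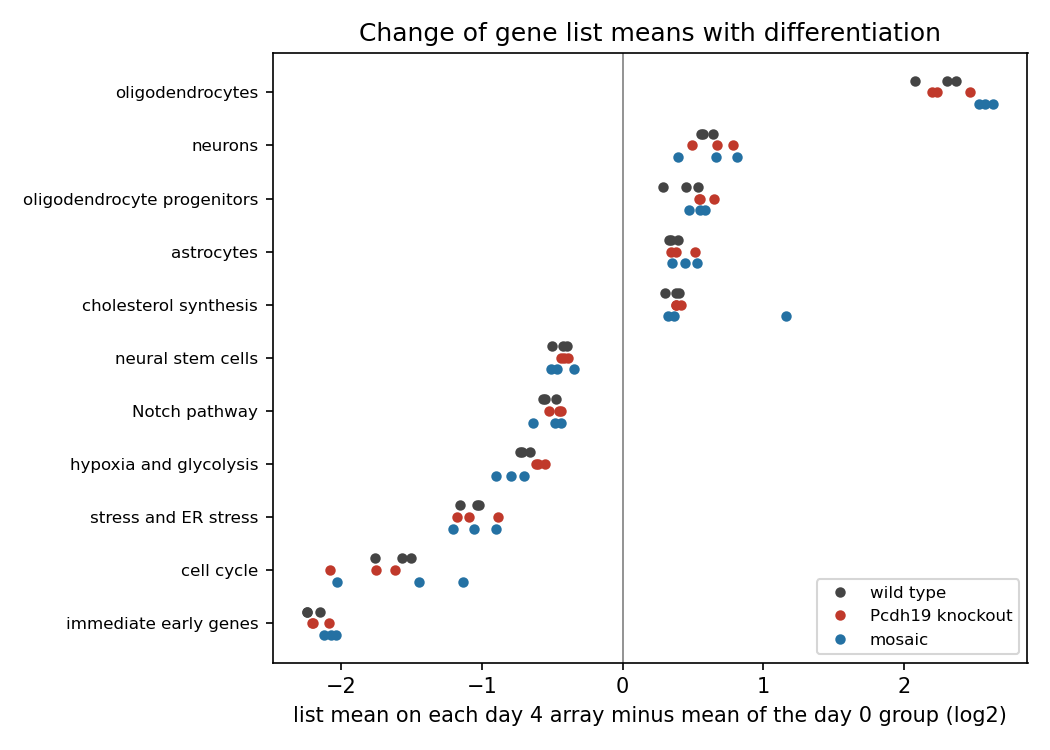
Change of 11 gene lists over differentiation, drawn as the list mean on each day 4 array minus the mean of the day 0 group of its genotype, on the log2 scale, with dots coloured by genotype. Oligodendrocyte and neuronal lists lie above 0 and immediate early, stress and cell cycle lists below 0 on all 9 day 4 arrays.

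The differentiation changes were shared between genotypes that have no array in common. Of the genes called in wild type and knockout cultures 1920 were higher in both and 2038 lower in both, against 491 and 386 for independent lists of those sizes, and 8 had opposite directions. For wild type and mosaic these were 1825 and 1891 against 471 and 369, with 7 opposite, and for knockout and mosaic 2143 and 1809 against 408 and 281, with 5. Across all 19016 genes, which are not independent replicates, Pearson's r between the log2 fold changes was 0.859 for wild type and knockout, 0.842 for wild type and mosaic and 0.900 for knockout and mosaic, with Spearman's rho of 0.663, 0.632 and 0.745. In all 3 genotypes 1685 genes, Mobp, Mag and Elavl3 among them, rose and 1699, among them Fos, Egr1 and Ccnb2, fell.

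At day 0 no single gene passed in limma for knockout against wild type, mosaic against wild type or mosaic against knockout. Unadjusted p was under 0.05 for 686, 817 and 806 genes (951 by chance). Even Pcdh19 did not pass, so 0 calls do not show that genotypes were alike. Pcdh19 had the fourth lowest p for knockout against wild type, behind Itgbl1 (0.56 ± 0.10), Krt71 (0.95 ± 0.18) and Zfp773 (0.51 ± 0.10, all adjusted p = 0.564), which were chosen after their values were seen. All other settings also gave 0 genes except the fit on the groups compared alone (1, Pcdh19) and the removal of single arrays. Without knockout replicate 1, Flrt1, a membrane protein gene, passed for knockout against wild type (-1.05, adjusted p = 0.00292) and for mosaic against knockout (0.85, adjusted p = 0.0446), and without wild type replicate 2, Serpina1e passed for mosaic against wild type (1.05, adjusted p = 0.028).

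Hypoxia and glycolysis genes were higher in mosaic than in knockout neurospheres at day 0. Of 21 genes 18 were higher and 3 lower, with a median of 0.26, adjusted p = 3.46e-08, and adjusted p = 0.343 with an estimated correlation, and this call held without any single array (highest 0.000157). The list means of the 3 mosaic and 3 knockout arrays overlapped, however (exact permutation p = 0.2, two-sided). Adm and Vegfa, secreted factors induced by low oxygen, differed by 0.44 ± 0.15 and 0.42 ± 0.24, and Slc2a1, a glucose transporter gene, by 0.41 ± 0.17. Against wild type 16 of 21 were higher in the mosaic (median 0.21, adjusted p = 0.000305, and adjusted p = 0.558 with an estimated correlation), and that call ended without wild type replicate 1 (0.321). The difference of list means from wild type, 0.171, was 0.0538 and 0.289 without wild type replicates 1 and 2 and 0.266 and 0.114 without mosaic replicates 1 and 3. The other list calls at day 0 all ended when some array was left out. Of the 12 list calls between genotypes at day 0, 3 had list means that did not overlap between the groups, which chance gives in 10% of lists. In every list called at day 0, 0 members passed over all genes and 0 adjusted over the list alone.

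Knockout neurospheres at day 0 had lower values of oligodendrocyte genes (18 of 23 lower, median -0.14, adjusted p = 0.0179), oligodendrocyte progenitor genes (15 of 19 lower, -0.09, 0.0219) and stress genes (21 of 24 lower, -0.09, 0.0476), and higher values of microglial genes (13 of 18 higher, 0.07, 0.0411) than the wild type. With an estimated correlation these adjusted p were 0.705, 0.607, 0.651 and 0.343. The oligodendrocyte call ended without wild type replicate 1 (0.0674), knockout replicate 1 (0.372) or knockout replicate 2 (0.404). For oligodendrocyte progenitors the call ended without wild type replicate 2 (0.0752) or 3 (0.351) or knockout replicate 1 (0.072) or 2 (0.303). Stress genes no longer passed without wild type replicate 2 (0.368) or knockout replicate 2 (0.894), nor microglial genes without wild type replicate 3 (0.338) or knockout replicate 1 (0.125) or 3 (0.0923). The difference of list means moved for oligodendrocyte genes from -0.145 to -0.0757, -0.0669 and -0.293 without knockout replicates 1, 2 and 3, and for microglial genes from 0.0896 to 0.0522 without wild type replicate 3. For oligodendrocyte progenitors it moved from -0.115 to -0.174 and -0.0735 without wild type replicates 1 and 3 and to -0.0574 and -0.189 without knockout replicates 2 and 3. For stress genes it moved from -0.0897 to -0.139 and -0.0404 without wild type replicates 1 and 2 and to -0.171 without knockout replicate 3, and it turned to 0.00442 without knockout replicate 2. After quantile normalization the microglial (0.0818) and stress calls (0.0612) ended, and with no filter the microglial call (0.0902).

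Mosaic neurospheres at day 0 had higher cell cycle genes (27 of 28 higher, median 0.14, adjusted p = 0.0218) and cholesterol synthesis genes (17 of 19 higher, 0.12, 0.0219) than the wild type. Neuronal genes (23 of 29 lower, -0.07, 0.0375), nonclustered protocadherins (11 of 12 lower, -0.10, 0.012) and immediate early genes (15 of 22 lower, -0.17, 0.0333) were lower. With an estimated correlation the adjusted p of these 5 lists were 0.85, 0.85, 0.761, 0.348 and 0.562. Pcdh19 is itself a nonclustered protocadherin, and that list was not tested without it. Cell cycle genes no longer passed without wild type replicate 1 (0.129) or mosaic replicate 1 (0.121) or 2 (0.203), and cholesterol genes without wild type replicate 1 (0.169) or 3 (0.194) or mosaic replicate 2 (0.148). The neuronal call ended without wild type replicate 1 (0.0814) or 3 (0.0682) or mosaic replicate 3 (0.188), the protocadherin call without mosaic replicate 1 (0.152), and the immediate early call without wild type replicate 2 (0.324) or mosaic replicate 3 (0.83) and after quantile normalization (0.05). Neuronal genes were also lower in mosaic than in knockout neurospheres (20 of 29, -0.09, adjusted p = 0.0372, and 0.761 with an estimated correlation). This ended without knockout replicate 1 (0.172) or 3 (0.385) or mosaic replicate 3 (0.196). Their difference of list means, -0.0842, was -0.139 and -0.0426 without knockout replicates 2 and 3. Against wild type that of immediate early genes, -0.107, was -0.0685 without wild type replicate 2 and -0.166 and -0.0166 without mosaic replicates 2 and 3, and that of cholesterol genes, 0.124, was 0.194 without wild type replicate 2.

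At day 4, 0 single genes passed in limma in any comparison of genotypes, while 2411 genes for knockout against wild type, 3026 for mosaic against wild type and 1155 for mosaic against knockout had an unadjusted p under 0.05, against 951 by chance. Among genes chosen after their values were seen, Gm21370 (-0.68 ± 0.10, adjusted p = 0.0619) and Kcnmb3, a potassium channel subunit gene (-0.82 ± 0.13, adjusted p = 0.0649), came closest for knockout against wild type. Gm21370 passed after quantile normalization (-0.70, adjusted p = 0.0319), and both passed with the filter at the 50th percentile (adjusted p = 0.028 and 0.0337). Without wild type replicate 3, the 5 genes Dppa2, Gm21370, Krt33a, Tagln and Tmem221 passed, all lower in the knockout, and without knockout replicate 2 there were 4, of which 4833420G17Rik was higher and Gm19461, Kcnmb3 and Lrrc17 were lower. For mosaic against wild type, Zfp972 (1.33 ± 0.20, adjusted p = 0.12) and Hnrnpa3 (0.78 ± 0.13, adjusted p = 0.12) passed only with the variance trend and robust estimation (0.0206 and 0.0238) among the planned fits on all arrays. Without wild type replicate 3 the 3 genes Map3k6, Tmem221 and Zfp972 passed, and without mosaic replicate 1 the count was 262 (138 up, 124 down). Without mosaic replicate 1, the 10 genes that passed for mosaic against knockout included Cenpe (0.99 ± 0.11) and Kif18a (0.91 ± 0.10), both of mitosis, with adjusted p = 0.00154. With the lowest-weight day 4 array of each genotype left out, a setting chosen after seeing the data, Mfsd4b2 (-0.99) and Wfikkn2 (-0.87) passed for mosaic against wild type, and 6 genes passed for mosaic against knockout, Kif18a (0.97) and Cenpe (0.95) among them. All other settings gave 0 genes in these 3 comparisons.

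Cell cycle, oligodendrocyte and cholesterol genes were higher in mosaic than in knockout cultures at day 4. All 28 cell cycle genes were higher, with a median of 0.37, among them Cenpe (0.67 ± 0.18), Mki67 (0.66 ± 0.21) and Aspm (0.65 ± 0.13), none of which passed over all genes. Of 23 oligodendrocyte genes 22 were higher, with a median of 0.34, among them Gjc3, a connexin gene (0.64 ± 0.15), and Tspan2 (0.56 ± 0.15), and all 19 cholesterol genes were higher, with a median of 0.32. Adjusted over the list alone 2, 2 and 1 members rose and 0 fell. The camera test gave adjusted p = 4.73e-11, 2.04e-08 and 2.96e-09, and with an estimated correlation the adjusted p were 0.444, 0.343 and 0.46. The list means of oligodendrocyte and cholesterol genes on the 3 mosaic arrays lay above those of the 3 knockout arrays, for which an exact permutation test gives its smallest possible two-sided p of 0.1, and those of the cell cycle genes overlapped (exact p = 0.3). Without mosaic replicate 3 the cholesterol call ended (0.408, with a difference of list means of 0.0516 in place of 0.324), while the other calls held without any single array, with highest adjusted p of 0.00188 and 0.000126. The difference of cell cycle list means, 0.352, was 0.15 without mosaic replicate 3, 0.598 without mosaic replicate 1 and 0.22 without knockout replicate 1. Of all 18 list calls between genotypes at day 4, 9 had list means that did not overlap, a count that is no separate support, as the lists were called on the same arrays. Neuroblast genes (15 of 21 lower, median -0.14, adjusted p = 0.047), neuronal genes (24 of 29 lower, -0.11, 0.0167) and Notch genes (17 of 23 lower, -0.11, 0.0377) were lower in the mosaic, with adjusted p = 0.637, 0.707 and 0.607 with an estimated correlation and 1, 0 and 0 members lower adjusted over the list alone. The neuroblast call ended without knockout replicate 1 (0.186) or 2 (0.277) or mosaic replicate 2 (0.134) or 3 (0.731), the neuronal call without knockout replicate 1 (0.544) or mosaic replicate 3 (0.945), and the Notch call without knockout replicate 1 (0.157) or 2 (0.125) or mosaic replicate 3 (0.459). The difference of list means of neuronal genes, -0.108, turned to 0.00646 without mosaic replicate 3 and was -0.202 without mosaic replicate 1 and -0.0409 and -0.186 without knockout replicates 1 and 3. That of neuroblast genes, -0.096, was -0.182 and -0.0129 without mosaic replicates 1 and 3 and -0.0634 without knockout replicate 2, and that of Notch genes, -0.0932, was -0.0349 without mosaic replicate 3. The neuroblast call also ended after quantile normalization (0.0654) and with the mean of a gene's probe sets (0.0875), and the Notch call with that mean (0.0626) and with the lowest-weight arrays left out (0.0629).

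**Figure D3:**
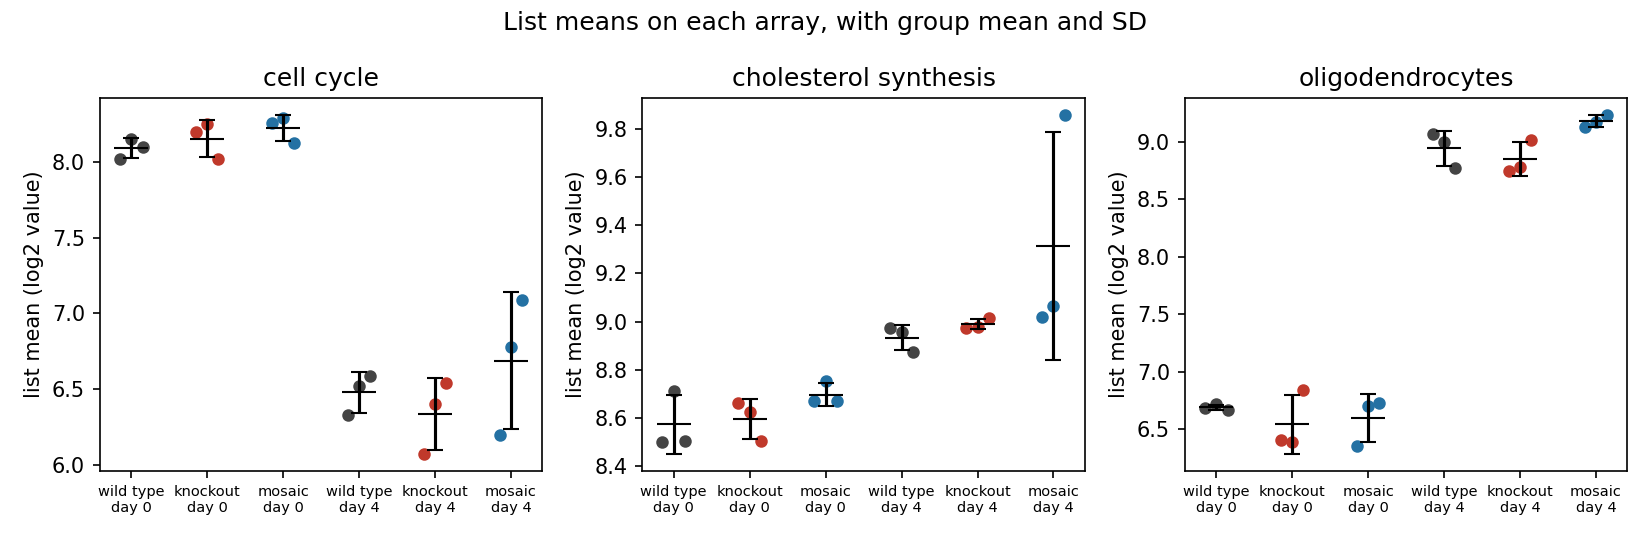
Mean log2 signal of the cell cycle, cholesterol synthesis and oligodendrocyte lists on each of the 18 arrays, by genotype and day, with group means and SDs. At day 4 the oligodendrocyte mean is 9.13 to 9.23 on the mosaic arrays and 8.75 to 9.02 on the knockout arrays, and mosaic replicate 3 stands above the other mosaic arrays for cholesterol synthesis (9.86 against 9.02 and 9.06).

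Mosaic cultures at day 4 also had higher cholesterol genes than the wild type, with 19 of 19 higher and a median of 0.42, among them Ebp (0.56 ± 0.16) and Sqle (0.44 ± 0.13), which did not pass over all genes. Adjusted over the list alone 8 rose and 0 fell. The list had adjusted p = 1.79e-07, and adjusted p = 0.557 with an estimated correlation, and the call held without any single array (highest 0.045, without mosaic replicate 3). The difference of list means fell without that array, from 0.380 to 0.107. Oligodendrocyte genes (21 of 23 higher, median 0.27, adjusted p = 0.00278, and adjusted p = 0.562 with an estimated correlation) no longer passed without wild type replicate 3 (0.0886). Cell cycle genes (26 of 28 higher, 0.22, adjusted p = 0.00863, and adjusted p = 0.843 with an estimated correlation) no longer passed without wild type replicate 1 (0.109) or mosaic replicate 3 (0.99). Their difference of list means, 0.211, was 0.0094 without mosaic replicate 3, 0.457 without mosaic replicate 1 and 0.136 without wild type replicate 1, and that of oligodendrocyte genes, 0.235, was 0.148 without wild type replicate 3. Adjusted over the list alone 0 oligodendrocyte genes and 1 cell cycle gene, Aspm (0.61 ± 0.13), rose. Genes of neuroblasts (19 of 21 lower, median -0.11, adjusted p = 0.047) and of regional patterning (20 of 29 lower, -0.14, 0.0375) were lower, with adjusted p = 0.637 and 0.39 with an estimated correlation and 2 and 0 members lower adjusted over the list alone. The neuroblast call ended without wild type replicate 1 (0.062) or 3 (0.114) or mosaic replicate 2 (0.0786) or 3 (0.619), and the patterning call without wild type replicate 1 (0.0787) or 2 (0.077) or mosaic replicate 2 (0.0784) or 3 (0.146). The difference of list means of neuroblast genes, -0.123, was -0.209 and -0.0397 without mosaic replicates 1 and 3. The patterning call also ended after quantile normalization (0.118), and the neuroblast call with no filter (0.0608) or the mean of a gene's probe sets (0.0614). Of the 8 lists called for mosaic against wild type at day 4, 4 were still called in the same direction after quantile normalization, namely cholesterol, oligodendrocyte, cell cycle and neuroblast genes.

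Knockout cultures at day 4 had higher synapse genes than the wild type, with 21 of 26 higher, a median of 0.10 and the glutamate receptor gene Grin2b at 0.34 ± 0.13, and lower cell cycle genes, with 23 of 28 lower and a median of -0.17. The adjusted p were 0.0136 and 0.0372, and 0.403 and 0.863 with an estimated correlation. The synapse call ended without wild type replicate 2 (0.0554) or knockout replicate 1 (0.168), and the cell cycle call without wild type replicate 2 (0.128) or 3 (0.278) or knockout replicate 1 (0.853). The cell cycle difference of list means, -0.141, was -0.215 and -0.0873 without wild type replicates 1 and 3 and -0.00948 and -0.242 without knockout replicates 1 and 3, and the synapse difference, 0.125, was 0.0655 without knockout replicate 1. The synapse call also ended with the mean of a gene's probe sets (0.0875), the cell cycle call with no filter (0.0581), and both with the lowest-weight arrays left out (0.264 and 0.0678). The synapse median lay at percentile 97.3 of 10000 random lists matched on mean level, 95% of which ran from -0.01 to 0.10, and the list means overlapped between the groups for both lists (exact permutation p = 0.2 and 0.6).

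Among 4 lists of other cell types, endothelial and ependymal genes were lower at day 4 in both the knockout and the mosaic, which share the wild type arrays they are compared with. Microglial genes passed in neither (median -0.08, adjusted p = 0.0884 in the knockout and -0.12, 0.0767 in the mosaic). Fibroblast and meningeal genes did not pass in the knockout (-0.05, adjusted p = 0.0943), nor did they for mosaic against knockout (-0.04, adjusted p = 0.322). Endothelial and mural genes were lower in 16 of 20 cases in the knockout (median -0.19, adjusted p = 0.000808) and 15 of 20 in the mosaic (-0.20, 0.00473), with the smooth muscle gene Tagln at -0.55 ± 0.13 and -0.47 ± 0.13. With an estimated correlation these adjusted p were 0.276 and 0.343, and both calls held without any single array (highest 0.0177 and 0.0215). The knockout call ended with the lowest-weight arrays left out (0.0648), and the mosaic call after quantile normalization (0.0714). Ependymal genes were lower in 12 of 14 cases (-0.13, 0.0235) and 11 of 14 (-0.12, 0.0476), with adjusted p = 0.373 and 0.432 with an estimated correlation. The ependymal call ended in the knockout without wild type replicate 3 (0.116) or knockout replicate 1 (0.0642), and in the mosaic without wild type replicate 3 (0.186) or mosaic replicate 1 (0.0774) or 3 (0.13). Both ended after quantile normalization (0.181 and 0.345), the knockout call also with the lowest-weight arrays left out (0.0563) and the mosaic call with no filter (0.0559). Fibroblast and meningeal genes were lower in the mosaic (14 of 19, -0.15, adjusted p = 0.0122, and adjusted p = 0.343 with an estimated correlation), and no longer passed without wild type replicate 1 (0.0735) or mosaic replicate 3 (0.0507) or after quantile normalization (0.136). Adjusted over the list alone 1 endothelial and mural gene, Tagln, fell in the knockout and 0 in the mosaic, 2 fibroblast genes fell in the mosaic, and 0 synapse, cell cycle or ependymal genes changed in these comparisons with the knockout. Over all probe sets the wild type day 4 arrays had a smaller SD (2.17 to 2.18) than the knockout (2.19 to 2.23) and mosaic arrays (2.19 to 2.22), and genes of low signal were shifted with it. In the lowest quintile of genes by mean level the median log2 fold change at day 4 was -0.13 for both comparisons with the wild type.

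**Figure D4:**
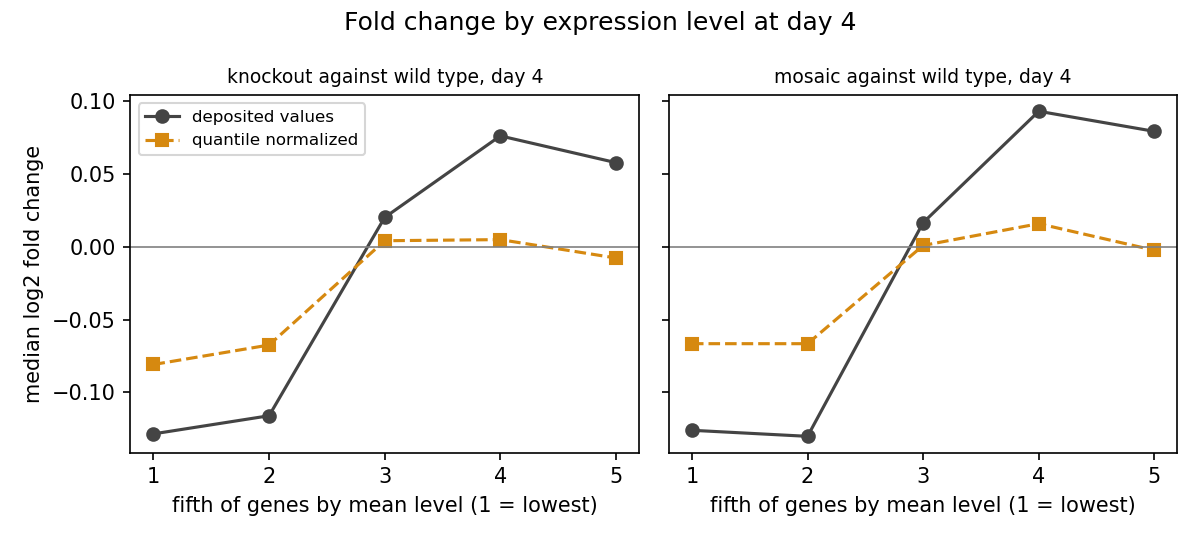
Median log2 fold change at day 4 against wild type in quintiles of genes by mean signal, for the knockout and for the mosaic, with the deposited values and after quantile normalization. With the deposited values the medians run from -0.13 in the lowest quintile to 0.06 (knockout) and 0.08 (mosaic) in the highest, and after quantile normalization from -0.08 and -0.07 to -0.01 and 0.00.

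The difference of differentiation between genotypes was tested gene by gene as an interaction, and 0 genes passed in limma. For knockout against wild type, mosaic against wild type and mosaic against knockout, Pcdh19 had 0.07, 0.27 and 0.20 (each ± 0.37, adjusted p = 0.971, 0.79 and 0.999). At an unadjusted p under 0.05 there were 1809, 2354 and 815 genes (951 by chance). Quantile normalization and the filter at the 50th percentile each gave 1 gene for knockout against wild type, Gm21370 (-0.98 and -0.95, adjusted p = 0.0369 and 0.0299). For mosaic against wild type, Zfp972 passed with the variance trend (1.77, adjusted p = 0.0479) and H2al3 in the fit on the groups compared alone (-1.25, adjusted p = 0.0429). Without knockout day 0 replicate 1, Flrt1 (1.23) and Gm21370 (-1.02) passed for knockout against wild type. With the lowest-weight day 4 arrays left out, Zfp820 (2.03), Wfikkn2 (-1.05) and Gata4 (-0.93) passed for mosaic against wild type. Without wild type day 4 replicate 3, Zfp972 (1.99) passed for the same comparison, and without mosaic day 4 replicate 1, Cenpe (1.07) for mosaic against knockout. All these genes were chosen after their values were seen, and the other settings gave 0.

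Genes whose level in the mosaic lay outside both genotypes, which mixing of unaffected wild type and knockout cells does not give, numbered 0 in limma on either day. At an unadjusted p under 0.05 there were 192 such genes at day 0 and 434 at day 4, and the lowest adjusted p was 1 on both days. Chosen after its values were seen, Aspm, a gene of the mitotic spindle, had the lowest p at day 4, with a mosaic level 0.61 ± 0.13 above wild type and 0.65 ± 0.13 above knockout. Every other setting, and the removal of each array in turn, also gave 0.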

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

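The tests that weigh explanations in this part were all chosen after the results they bear on had been seen, and so were the list tests without single arrays or without the lowest-weight day 4 arrays, and the differences of list means without single arrays; the list tests themselves were set before. What drew attention in each of the following lists is that its change over differentiation differed between genotypes by the test of that difference (camera on the interaction). In these 17 results 0 single genes passed over all genes, and with an estimated correlation none of the lists passed (lowest adjusted p = 0.292, 0.322 and 0.46 over the lists of knockout against wild type, mosaic against wild type and mosaic against knockout).

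Between knockout and wild type, synapse genes changed upward by more in the knockout (median interaction 0.11, 21 of 26 members above 0, adjusted p = 0.0256). Cell cycle genes had a lower change in the knockout (-0.25, 23 of 28 below 0, adjusted p = 0.0221), as had ependymal (-0.16, 0.0375), microglial (-0.18, 0.00972), endothelial and mural (-0.18, 0.00813) and fibroblast genes (-0.06, 0.0302). The microglial call held without any single array (highest 0.0462). Leaving out knockout day 4 replicate 1 ended the calls of cell cycle (0.471), synapse (0.15), ependymal (0.0812), endothelial (0.0578) and fibroblast genes (0.131). Without that array the interaction of list means was -0.0724 in place of -0.204 for cell cycle and 0.0821 in place of 0.142 for synapse genes, and without wild type day 0 replicate 3 it was -0.112 in place of -0.173 for ependymal genes. The synapse call also ended without wild type day 0 replicate 2 (0.0637), wild type day 4 replicate 2 (0.068), knockout day 0 replicate 1 (0.0653) or knockout day 4 replicate 2 (0.0529). Cell cycle genes also no longer passed without wild type day 0 replicate 1 (0.0754), wild type day 4 replicate 2 (0.0699) or 3 (0.136), or knockout day 0 replicate 1 (0.0749) or 2 (0.101). For ependymal genes the further arrays were wild type day 0 replicate 3 (0.244), wild type day 4 replicate 3 (0.112), knockout day 0 replicate 1 (0.0508) or 3 (0.144) and knockout day 4 replicate 3 (0.0606), and for fibroblast genes wild type day 0 replicate 2 (0.0637) and day 4 replicate 1 (0.109). After quantile normalization the cell cycle call was still made (0.0155). The synapse (0.0629), ependymal (0.206), microglial (0.111), endothelial (0.0759) and fibroblast calls (0.193) ended. With the lowest-weight day 4 arrays left out synapse (0.196), ependymal (0.067), endothelial (0.114) and fibroblast genes (0.355) no longer passed. With the mean of a gene's probe sets the synapse (0.18) and fibroblast calls (0.0503) ended, and with no filter the endothelial call (0.0555).

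Between mosaic and wild type, oligodendrocyte genes changed upward by more in the mosaic (0.36, 20 of 23 above 0, adjusted p = 0.00135), as did cholesterol genes (0.24, 0.0112). Microglial (-0.17, 0.0218), endothelial and mural (-0.26, 0.0128), fibroblast (-0.13, 0.0222), interferon (-0.11, 0.0411) and regional patterning genes (-0.14, 0.0179) had a lower change in the mosaic. The oligodendrocyte and endothelial calls held without any single array (highest 0.0293 and 0.0405), although without mosaic day 0 replicate 1 the oligodendrocyte interaction of list means was 0.209 in place of 0.328. That of cholesterol genes, 0.256, was -0.0167 and 0.404 without mosaic day 4 replicates 3 and 1. Without mosaic day 4 replicate 3 the calls of cholesterol (0.799, with the direction turned), microglial (0.0572), fibroblast (0.0712) and patterning genes (0.0655) ended. Without wild type day 0 replicate 2 those of cholesterol (0.0802), fibroblast (0.0518), interferon (0.0717) and patterning genes (0.05) ended. Microglial genes also no longer passed without wild type day 0 replicate 3 (0.0776), mosaic day 0 replicate 3 (0.052) or wild type day 4 replicate 2 (0.0592), nor fibroblast genes without wild type day 4 replicate 1 (0.0822). The interferon call ended too without mosaic day 0 replicate 2 (0.0511), mosaic day 4 replicate 1 (0.0639) or wild type day 4 replicate 1, 2 or 3 (0.0514, 0.0576 and 0.0571). After quantile normalization 3 of these 7 calls were still made, and those of microglial (0.249), endothelial (0.137), fibroblast (0.181) and interferon genes (0.195) ended. The interferon call also ended with no filter (0.0842), with the replicate number as a block and with the lowest-weight day 4 arrays left out (0.0759).

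Between mosaic and knockout, cell cycle (0.34, 23 of 28 above 0, adjusted p = 4.52e-05), oligodendrocyte (0.27, 0.000167) and cholesterol genes (0.24, 0.00354) had a higher change in the mosaic and hypoxia genes a lower one (-0.19, 0.000592). All 4 were still called after quantile normalization. The hypoxia call held without any single array (highest 0.0302) but ended with the lowest-weight day 4 arrays left out (0.067). Cell cycle genes no longer passed without knockout day 4 replicate 1 (0.0702) or mosaic day 4 replicate 3 (0.175), oligodendrocyte genes without knockout day 0 replicate 3 (0.102), and cholesterol genes without mosaic day 4 replicate 3 (0.307, with the direction turned). The interaction of list means was 0.282 for cell cycle genes, and 0.15 without knockout day 4 replicate 1, 0.528 without mosaic day 4 replicate 1 and 0.0805 without replicate 3. For cholesterol genes it was 0.224, and 0.372, 0.348 and -0.049 without mosaic day 4 replicates 1, 2 and 3, and for oligodendrocyte genes 0.278, with 0.13 and 0.158 without knockout day 0 replicate 3 and mosaic day 0 replicate 1.

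The first pattern weighed is the lower signal at day 4 of markers of other cell types, where endothelial and ependymal lists passed in knockout and mosaic cultures and the fibroblast list in the mosaic, while microglial genes passed in neither and fibroblast genes not in the knockout (percentiles 71.7, 49.6 and 76.5 of 10000 random lists matched on level). If the wider spread of those arrays were the cause, random genes of the same level should fall as far as the 71 genes of the 4 lists (medians -0.13 and -0.16, mean level 4.80), and 95% of the medians of matched lists ran from -0.15 to -0.04 in the knockout and from -0.16 to -0.05 in the mosaic, with the markers at percentiles 13.2 and 2.79. The endothelial list alone lay lower, at percentiles 2.78 and 2.29, while ependymal genes lay at 32.1 and 37.7 and fibroblast genes in the mosaic at 14.7, and after quantile normalization its call remained in the knockout (0.0136) and ended in the mosaic (0.0714), so array spread cannot be told apart from a fall of these markers, under a requirement on each list alone that was added after the percentiles were seen. Fewer cells of these types cannot be told apart from it either, because only the 2 members Acta2 and Cspg4 lay above the 75th percentile of the arrays, with medians of -0.163 in the knockout and -0.0506 in the mosaic. An effect of genotype on such cells stays open and was not tested otherwise.

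The second pattern is the higher signal of cell cycle, cholesterol and oligodendrocyte genes in mosaic than in knockout cultures at day 4. Array spread does not account for it, since each list's median lay at percentile 100 of 10000 lists matched on level. Without mosaic replicate 3, the array with a Pcdh19 level like the knockout's, the difference of list means went from 0.324 to 0.0516 for cholesterol genes, which is consistent with that array alone carrying it. For oligodendrocyte genes it went from 0.330 to 0.303, against SDs of 0.05 in the mosaic and 0.15 in the knockout, so that array alone does not carry that difference. For cell cycle genes it went from 0.352 to 0.15 with the list test still past (0.00188), but to 0.598 without mosaic replicate 1 and to 0.22 without knockout replicate 1, which leaves the part of any single array open, and an effect of mixing the genotypes stays a hypothesis for the oligodendrocyte and cell cycle genes.

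The third pattern is that Y-linked genes had signal on samples labelled female, with Eif2s3y (8.24 to 9.04), Kdm5d (6.85 to 8.20) and Uty (6.96 to 7.97) above the array median on 18 of 18 arrays, while Xist, the RNA of the inactive X chromosome (2.69 to 3.98), and the Y-linked Usp9y (2.67 to 3.40) lay below it on all 18. Cross-hybridisation of Kdm5c to the Kdm5d probe set is argued against by a fall of Kdm5d over differentiation larger than that of Kdm5c by -0.494 ± 0.0966 (SE). For Uty and Kdm6a the difference was 0.352 ± 0.0662 the other way, so cross-hybridisation of Kdm6a may account for the signal of Uty. For Eif2s3y cross-hybridisation was not examined, as the probe sets of its X-linked homologue Eif2s3x are annotated to several genes. Male cells cannot be told apart from other sources of this signal, because a rank against the array median compares different probes with no measured background. Probe sets of Xist that do not respond cannot be told apart from absent Xist either, as on 0 arrays were the Y-linked genes low. All groups share the pattern, so that it separates none of the comparisons.

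Other splits of the arrays were set beside each count of genes. For differentiation, 1 of the 10 splits of the 6 arrays, the real one, gave as many genes (6386, 5211 and 4989 in wild type, knockout and mosaic cultures). Highest other counts were 1, 0 and 0. With 10 splits the share cannot go under 0.05. In the genotype comparisons, the interactions and the mosaic outside both genotypes the real count was 0, which every split reaches whatever the data (10 of 10, and 100 of 100 drawn for the interactions and the mosaic outside both), so these splits say nothing about chance. Their highest other counts were 0 and 1 for knockout against wild type at day 0 and day 4, 1 and 1 for mosaic against wild type and 2 and 3 for mosaic against knockout. For the interactions they were 1, 3 and 7 in that order, and for the mosaic outside both genotypes 1 on each day.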

How the results depend on the processing

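The removal of the lowest-weight day 4 arrays and the list tests, differences of list means and Pcdh19 values without single arrays or under other settings were chosen after seeing the data; the other alternatives were planned. Each differentiation count stayed within 1.5 times its value (6386, 5211 and 4989 in wild type, knockout and mosaic cultures) under quantile normalization (6648, 5375, 5156), a common median (5936, 5090, 4958), no filter (6118, 4972, 4753), the mean of probe sets (6309, 5124, 4907), the variance trend (6486, 5483, 5320), array weights (7016, 5577, 5142) and the groups compared alone (6107, 4170, 3763). Counts fell under a minimum change of 1.5-fold (2402, 2132 and 2166) and, in the wild type, under an adjusted p below 0.01 (4046), because these thresholds are stricter. Counts of 0 became 1 for knockout against wild type at day 4 and 1 for its interaction under quantile normalization, 2 and 1 with the 50th percentile filter (fewer genes tested), 2 for mosaic against wild type at day 4 and 1 for its interaction with the variance trend, and, on the groups compared alone, 1 for knockout against wild type at day 0 and 1 for the mosaic interaction with wild type. That day 0 gene was Pcdh19, at -1.27 as in the full fit but with adjusted p = 0.0445. Without the lowest-weight day 4 arrays the counts were 2 for mosaic against wild type at day 4, 6 for mosaic against knockout at day 4 and 3 for the mosaic interaction with wild type. Except where stated, the cause was not tested.

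Leaving out each array in turn gave 5038 to 5725 genes for differentiation of wild type, 4237 to 4849 of knockout and 4126 to 4523 of mosaic cultures. The ranges for knockout against wild type were 0 to 1 at day 0 and 0 to 5 at day 4, for mosaic against wild type 0 to 1 and 0 to 262, and for mosaic against knockout 0 to 1 and 0 to 10. The interactions in that order gave 0 to 2, 0 to 1 and 0 to 1, and the mosaic outside both genotypes 0 to 0. Pcdh19 ranged from -1.35 to -1.21 and -1.28 to -1.12 for knockout against wild type at day 0 and day 4, -0.94 to -0.60 and -0.86 to -0.08 for mosaic against wild type, and 0.33 to 0.67 and 0.34 to 1.12 for mosaic against knockout. The cholesterol interaction had adjusted p from 2.27e-05 to 0.799 for mosaic against wild type and from 8.95e-07 to 0.307 for mosaic against knockout, and its direction turned in both without mosaic day 4 replicate 3. The cause was not tested. Named genes lost their call in 153 fits, over 31 of 321 gene results, and 0 reversed. List calls were lost in 287 fits, over 94 of 97 calls. Leaving out some array moved the difference of list means by over 1.5 times in 8 of 12 list calls between genotypes at day 0, 11 of 18 at day 4 and 8 of 17 interactions.

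Of the 97 list calls 3 were made with an estimated correlation, because that test allows for the correlation measured between list members, and 55 were also called in the same direction by fry (70 calls in all), 79 after quantile normalization (81), 91 with no filter (93) and 90 with the mean of probe sets (91). With the replicate number as a replicate block the differentiation counts were 6328, 5208 and 4984, all other counts stayed 0, and 97 lists passed, 95 of them also called without it, while ependymal genes for mosaic against wild type at day 4 (0.0531) and the interferon interaction for mosaic against wild type (0.054) did not. Same-numbered arrays had correlations of their deviations of -0.146 to 0.165 (median 0.0261) over 45 pairs, 4 of them over 0.1, and in 0 of 15 pairs of groups were all 3 over 0.1, so the numbers were not taken to pair the arrays. An array correlated best with its own number in 25 of 45 comparisons, where chance gives 15. All day 0 and day 4 pairs of a genotype were above 0 (0.0153 to 0.164), a hint of pairing from the data and not from the design. Such pairs were not fitted as blocks. No offset was added, since the values were already on a log scale. Signal over background was not at hand, so how far the changes of dim genes, markers of rare cell types among them, are compressed is not known.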

Other observations

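The contrasts averaged over days in this part were chosen after the results had been seen, and the hypotheses on immediate early genes were framed after their fall was seen, with their gene lists and bounds written before those lists were measured. Adhesion genes moved both ways over differentiation of wild type cultures. Of 31 cadherins and adhesion partners 6 rose and 9 fell, also adjusted over the list alone, with the cadherin gene Cdh11 at 1.19 and the catenin gene Ctnna2 at 0.96, and with Fat3 at -1.24 and Celsr1, of planar cell polarity, at -0.88. In knockout cultures these genes stood at 1.26, 1.25, -1.05 and -0.76 and in mosaic cultures at 1.39, 1.31, -0.90 and -0.90, all called, and the list as a set passed in no genotype (adjusted p = 0.532, 0.915 and 0.862). Its median, mean and test differed in sign in each genotype.

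Members of signalling lists that did not pass as sets also changed in wild type cultures. Of 17 targets of BMP and TGF-beta 5 rose and 5 fell (6 and 5 adjusted over the list alone), with Id3 and Id1, transcriptional inhibitors induced by BMP, at -1.42 and -1.14 (adjusted p = 0.871 for the list). Bmp4 itself rose by 1.58 in knockout and 1.66 in mosaic cultures, and in the wild type its log2 fold change was 0.81 (adjusted p = 0.0802), while the difference between genotypes passed for 0 genes. Of 19 Wnt targets 6 rose and 4 fell, also adjusted over the list alone, with the Wnt inhibitor gene Apcdd1 at -2.23 (list adjusted p = 0.784). Of 11 targets of Shh 4 rose and 2 fell (4 and 4 adjusted over the list alone), with Nkx6-2, a transcription factor of oligodendrocytes, at 1.42 (list adjusted p = 0.871). Among markers of other cell types Pdgfrb, the growth factor receptor of mural cells, rose by 2.06 and Ogn, a matrix gene of fibroblasts, by 1.66, while the endothelial and fibroblast lists did not pass (adjusted p = 0.264 and 0.378). Meis2, of regional patterning, fell by 0.89, and the coactivator gene Ncoa3, of steroid hormone signalling, by 0.70, with list adjusted p of 0.883 and 0.974.

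Averaged over both days, 0 genes passed in limma for knockout against wild type, with 1152 at an unadjusted p under 0.05, and 0 for mosaic against wild type or against knockout, with 1401 and 1131. The lowest p for knockout against wild type belonged to Pcdh19 (-1.24 ± 0.19, adjusted p = 0.0642), Zfp773, a zinc finger gene (0.45 ± 0.07, adjusted p = 0.0642), and Armcx1, an X-linked gene (-0.60 ± 0.10, adjusted p = 0.0696). All 3 passed with array weights (adjusted p = 0.0291, 0.0291 and 0.0297) and after quantile normalization (0.0436 each), and 2 of them with a common median, where Armcx1 had adjusted p = 0.115.

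Lower ERK signalling at day 4, a hypothesis for the fall of the immediate early genes, was tested through 12 feedback genes not on the immediate early list. It predicted a median of -0.5 or lower in every genotype, and the medians were -0.13, -0.11 and -0.23 in wild type, knockout and mosaic cultures, so the prediction was not reached (highest median -0.105). The bound set against the hypothesis, a median above -0.25 in every genotype, was met. The 95% bootstrap intervals over genes ran from -0.94 to 0.06, -1.04 to 0.19 and -0.64 to 0.08. A requirement that these intervals clear the bound was added after the medians were seen, and with it the test stays open. In the wild type 6 of the 12 genes fell, among them Dusp5 (-1.84), Spry1 (-1.67) and Dusp4 (-0.87), and 2 rose, Spred1 (0.40) and Etv4 (0.35).

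Heat shock or handling stress at day 0, the other hypothesis, predicted the same median of -0.5 in 11 heat shock genes outside the stress list. The medians were -0.23, -0.18 and -0.28. Their 95% bootstrap intervals, from -0.44 to 0.36, -0.38 to -0.00359 and -0.32 to -0.00522, all left out -0.5. The bound against the hypothesis was not met in the mosaic. The list leaves out Hspa1a and Hspa1b, which fell in all 3 genotypes, so the test cannot decide the hypothesis. In the wild type 3 of the 11 genes fell, Dnajb1 (-0.44), Hsph1 (-0.48) and Hspe1 (-0.48), and 1, Hspa4 (0.36), rose.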
